A study of Sorghum bicolor with 24 samples.

How the data were processed

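Gene expression was measured by RNA sequencing in sorghum roots, in 24 libraries forming 8 groups of 3. The deposited data hold 2 tables, each with 12 libraries in 4 groups. The P table compares phosphorus deficiency with mock at days 4 and 7. The GR table compares GR245DS, a synthetic strigolactone analogue, with mock at 3 h and 6 h. Whether the replicates of a group are separate plants or separate cultures is not stated, so the p-values measure the spread between these samples.

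Per the labels' protocols, total RNA was extracted with the RNAprep Pure Plant Kit, and 1 µg per sample entered libraries made with the Hieff NGS Ultima Dual-mode mRNA kit. Whether the libraries were stranded is not given in the sources used here. Per the submitters' processing notes, the tools were fastp, HISAT2, featureCounts and DESeq2 1.22.1, with no role or order stated. Per the file headers, the deposited columns hold a raw count per gene and library, an FPKM per gene and library made by the authors, and an adjusted p-value (FDR) and a log2 fold change per comparison from the authors' DESeq2 fit. The count columns held whole numbers throughout. The authors' FPKM were not used here, and their log2 fold changes and calls were used only for a comparison of direction, where they are named as the authors' deposited table.

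The P table lists 35907 genes, of which 34129 carry a Sobic identifier and 1778 were predicted by the authors. The GR table lists 35842 genes, with the same 34129 Sobic identifiers and 1713 predicted genes. All per-library columns were matched to a sample by their names. The genome build is not stated and 0 of the Sobic identifiers occur in the reference gene table, so no positions are given and gene names are the descriptions in the deposited tables. Such a name comes from similarity to a known protein.

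Total counts ranged from 32631226 to 45292506 per library in the P table and from 31677623 to 38706195 in the GR table. Values are given as CPM (the cpm function of edgeR, which divides counts by the library total scaled with its TMM factor), as mean ± SD over 3 libraries. Folds are ratios of these means. Where all libraries of a group held 0 counts, the fold is a lower bound against a floor of 3 counts per library. Where a group held 1 to 3 counts in all, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only.

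The 12 libraries of a table were fitted together with 1 mean per group, and each treatment was compared with the mock of its own time. The test was the quasi-likelihood test of edgeR 4.0.16 (robust, TMM scaling, genes kept by filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p 0.05. This left 25137 genes in the P table and 24814 in the GR table. The common dispersion was 0.0408 in the P table and 0.136 in the GR table. Interactions tested whether a response differed between the times, and the mock groups of the times were compared as background. The words rose, fell, higher and lower describe genes past the threshold unless a value is said to miss it.

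A set of 36 gene lists was fixed before the data were examined, with membership by words in the gene descriptions. They cover phosphate and strigolactone biology, other hormones, transport, detoxification and cell type markers. Each list was tested with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists of a comparison). Camera with an estimated correlation, fry, which tests a list without reference to other genes, and camera with a replicate block were alternatives. For the P table, the phosphate transporter and membrane lipid remodelling lists kept their calls with an estimated correlation at both days. No list of the GR table kept its call under that setting.

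Named genes were chosen by a rule fixed before the data were examined. For each treatment comparison it takes the 6 genes with the largest change in each direction among those past the threshold with a description, a mean of at least 5 CPM in the higher group and no overlap between the groups. It adds the 2 members of each list central to that treatment with the smallest adjusted p (6 for strigolactone biosynthesis), and the member with the smallest adjusted p of any other list that passed. For the interactions it takes 3 genes per direction. Genes outside the rule are said to have been chosen after their values were seen.

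The alternatives were RLE size factors, scaling by total counts only, DESeq2 1.42.0, no filter on low counts, a filter of 30 reads in 3 libraries, a fit of only the 2 groups compared, the replicate number as a block, leaving out each library in turn, and a threshold of at least 2-fold. For agreement between comparisons, the alternative was to use only genes called in either. Leaving out the third replicates of all GR groups was chosen after seeing the data. In the GR table the deviations of libraries with the same replicate number correlated across genes in all 18 pairs of libraries from different groups (r between 0.139 and 0.76). Pairs with different numbers had r from -0.59 to 0.296, which overlaps this range, so the numbers pair these samples only in part. The block is therefore given beside the GR results where it changes a call or a count.

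The fit was tested on simulated data with the fitted means and dispersions and 200 changed genes per comparison. edgeR recovered 51.4% of 2-fold changes in either P comparison, and 94.3% (day 4) and 92.9% (day 7) of 4-fold changes. In the GR table it recovered 14.3% of 2-fold and 62.9% of 4-fold changes at 3 h, and 10% and 61.4% at 6 h. False calls made up 5.9%, 5.4%, 3.6% and 10.5% of its calls at day 4, day 7, 3 h and 6 h, against 23%, 23.3%, 41.7% and 38.4% for DESeq2. The edgeR rates rest on only 7, 6, 2 and 6 false calls, from a single simulated data set per comparison. The data were drawn with the dispersions of edgeR on genes kept by its filter, which may favour edgeR over DESeq2. All other genes were simulated without a change, and the libraries were drawn without the pairing by replicate number. The real P comparisons called 9713 genes at day 4 and 8958 at day 7, so these rates may not hold for the real data. Camera recovered the shifted list in each comparison, but the simulated genes were independent of each other, so its rate of false lists among correlated genes was not tested. Tables were handled with Python 3.11.15 and pandas 2.3.3.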

Results

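Roots of sorghum (Sorghum bicolor) were sequenced in 2 experiments. Phosphorus deficiency is a condition in which many plants raise phosphate uptake and the synthesis of strigolactones, hormones made from carotenoids that roots also release into the soil. The P table asks which root transcripts differ between phosphorus deficiency and mock after 4 and 7 days. The GR table asks which transcripts respond to GR245DS, a synthetic strigolactone analogue, after 3 h and 6 h. Each of the 8 groups has 3 libraries, with 32631226 to 45292506 counts per library in the P table and 31677623 to 38706195 in the GR table. Phosphate levels in the plants or in the medium are not given in the sources used here.

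Most called genes of 4 lists of the phosphate starvation response were lower in the libraries labelled P deficiency than in those labelled mock, opposite to their usual induction by phosphate shortage. Of the 90 tested members of these lists (SPX domain proteins, phosphate transporters, purple acid phosphatases and membrane lipid remodelling), 57 were lower and 14 higher at day 4, and 55 were lower and 13 higher at day 7. The list of phosphate starvation regulators did not pass with camera at either day. At day 4, 4 of its 17 members were lower and 1 higher (camera adjusted p = 0.238; 0.00179 with fry, which called it lower). At day 7 it departed from this pattern, with 4 lower and 6 higher (0.906; 0.0512 with fry). The mean log2(CPM + 1) of the 90 members was at most 3.54 in any library labelled P deficiency and at least 5.63 in any library labelled mock. In the authors' deposited table, the P deficiency columns name P deficiency before mock, and the fold changes had the sign of labelled P deficiency over labelled mock for only 1.5% of genes at day 4 and 0.5% at day 7. The GR columns name mock before GR245DS, and there 99.7% of genes at 3 h and 97.4% at 6 h had the sign of GR245DS over mock. By the deposited labels, both sets of columns thus give the group named last over the group named before it. With only the library labels of the P table exchanged, the P columns would instead give the group named first over the group named last. With the comparison names exchanged as well, they would still give the group named last over the group named first. These columns therefore cannot decide whether the labels were exchanged. All directions for the P table are stated by the deposited library labels.

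At day 4, the libraries labelled P deficiency held far fewer transcripts of the phosphate signalling, uptake and recycling genes than the libraries labelled mock. SPX domain proteins bind inositol pyrophosphates and restrain the phosphate starvation response. SPX1 (Sobic.004G084900) was at 2.2 ± 0.313 CPM against 255 ± 11.7 (log2 fold change -6.85 ± 0.14, SE, n = 3, edgeR adjusted p = 9.01e-12), and SPX3 (Sobic.001G259100) was 812-fold lower, at 0.706 against 573 CPM. The phosphate transporter PHT1-11 (Sobic.003G243400) had 0 counts in the libraries labelled P deficiency and 52.3 ± 12.2 CPM in mock, at least 704-fold lower, while PHT1-3 (Sobic.001G234900) was at 0.77 against 296 CPM. A glycerol-3-phosphate transporter (Sobic.006G173000) was 76.5-fold lower. Purple acid phosphatases release phosphate from organic compounds: PAP15 (Sobic.007G091100) was 1850-fold lower and the probably inactive PAP1 (Sobic.008G140100) 84.2-fold lower. Ribonuclease 1 (Sobic.007G137700) was at 11.1 against 122 CPM.

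Enzymes that replace phospholipids with lipids free of phosphate followed the same direction at day 4. The sulfolipid synthase SQD2 (Sobic.003G076900) was at 5.69 ± 0.747 against 1500 ± 31 CPM, and UDP-sulfoquinovose synthase (Sobic.009G123300) was 26.7-fold lower. Monogalactosyldiacylglycerol synthase 2 (Sobic.007G211900) was at 0.034 against 341 CPM. The glycerophosphodiester phosphodiesterase GDPD2 (Sobic.006G054800) was 11100-fold lower (95% counting interval 3430 to 48700). The ABC transporter B family member 14 (Sobic.007G042600) was at 0.017 against 339 CPM, a ratio of 19900 (5610 to 167000). A serine carboxypeptidase (Sobic.003G195700) and an 11-beta-hydroxysteroid dehydrogenase (Sobic.008G187200) had 0 counts in the libraries labelled P deficiency and were at least 547-fold and at least 426-fold lower. The few counts of MGD synthase 2 and ABC transporter B14 in the libraries labelled P deficiency came from replicate 3 and those of GDPD2 from replicate 2, and without these libraries the fitted log2 fold changes were -16.64, -16.62 and -16.18. The libraries labelled P deficiency that were left then held 0 counts of the gene, so these values are not measured sizes.

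The list tests at day 4 followed these genes. With camera, 14 of 20 phosphate transporters were lower and 1 higher (15 lower and 1 higher adjusted over the list alone, adjusted p = 5.27e-09), and 22 of 33 membrane lipid remodelling genes were lower and 5 higher (the same counts adjusted over the list alone, 9.71e-09). Among SPX domain proteins 8 of 13 were lower and 2 higher (the same adjusted over the list alone, 2.01e-05, with adjusted p = 0.0634 with an estimated correlation). Of 26 purple acid phosphatases, 14 were lower and 6 higher (15 and 7 adjusted over the list alone, 3.34e-05, with adjusted p = 0.0634 with an estimated correlation).

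**Figure D1:**
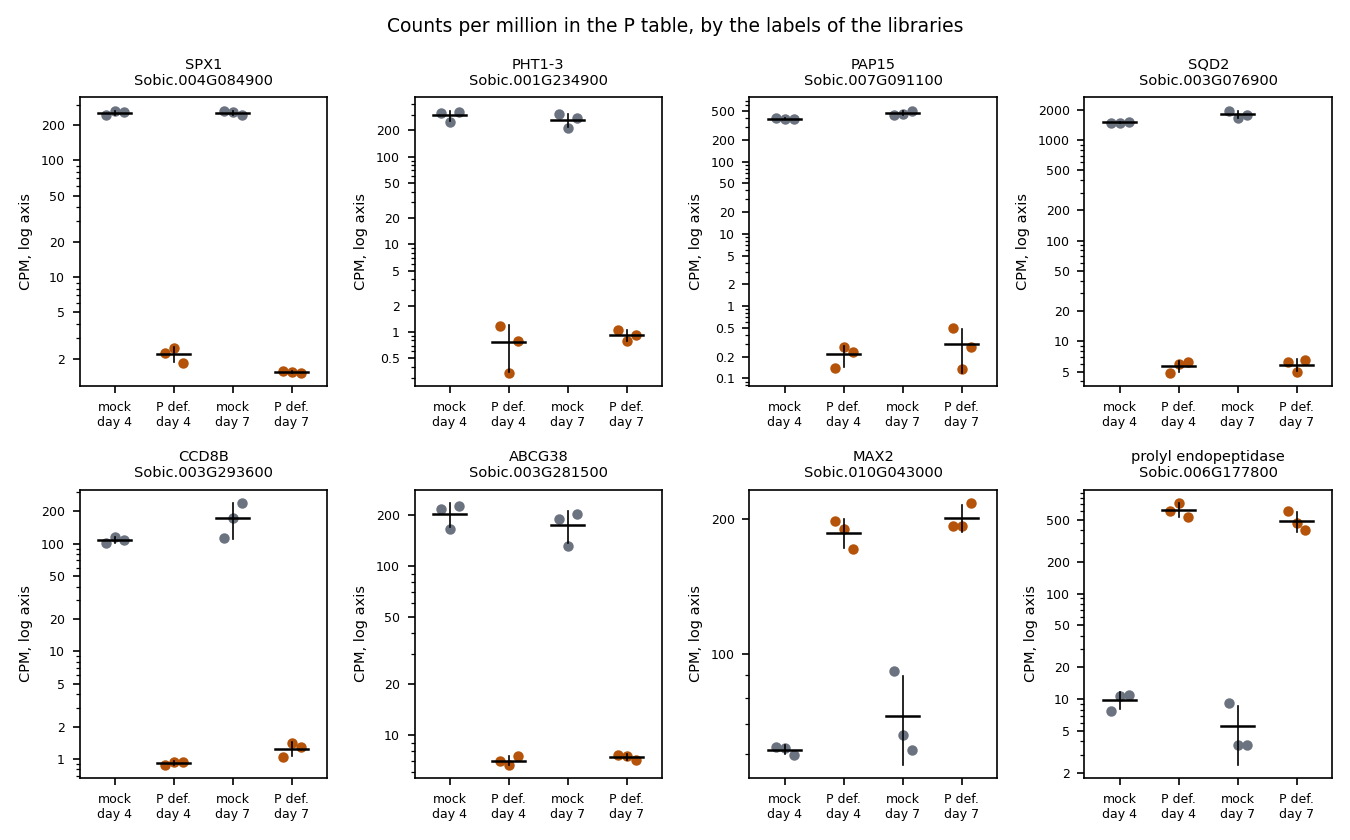
CPM on a log axis of phosphate and strigolactone genes in the 12 libraries of the P table, by deposited label and day. Points are libraries and marks with bars the mean and SD of 3 libraries, and SPX1 was at 2.2 CPM in the libraries labelled P deficiency and 255 CPM in those labelled mock at day 4.

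Strigolactone synthesis genes were split at day 4. The carotenoid cleavage dioxygenase CCD8-B (Sobic.003G293600) was at 0.918 ± 0.0362 CPM in the libraries labelled P deficiency against 108 ± 6.34 in mock (log2 fold change -6.88 ± 0.28, SE, n = 3, edgeR adjusted p = 1.47e-09). The carotene isomerase D27 (Sobic.005G168200) was 34.5-fold lower and CCD7 (Sobic.006G170300) 19.0-fold lower, at 6.94 CPM in mock. Another D27 gene (Sobic.009G030800) was higher, at 7.45 against 4.74 CPM, though its call ended without P deficiency replicate 1 or 2 or mock replicate 1 or 3 (log2 fold change 0.45 to 0.62). A CCD8-A gene (Sobic.005G002500) was also higher, at 2.2 against 0.661 CPM. A second CCD8-A gene (Sobic.007G170300) missed the threshold (3.38 against 4.46 CPM, adjusted p = 0.545). The synthesis list, with 3 of 6 members lower and 2 higher, did not pass with camera (adjusted p = 0.0623), while fry called it lower (5.95e-06) and camera with an estimated correlation did not (0.294). The precursor enzyme deoxyxylulose phosphate synthase 2 (Sobic.002G064700) was 27.2-fold lower, in a carotenoid and MEP pathway list with 11 of 23 members lower and 3 higher (adjusted p = 0.0205; adjusted p = 0.0988 with an estimated correlation).

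Genes of strigolactone perception moved the other way or apart at day 4. The F-box gene MAX2 (Sobic.010G043000) was at 186 ± 14.1 CPM in the libraries labelled P deficiency against 61.4 ± 1.48 in mock. A weakly expressed D14 receptor gene (Sobic.009G254700) was at 0.0379 against 2.65 CPM, with a fitted log2 fold change of -5.90, and -9.62 without P deficiency replicate 2. Its counts in the libraries labelled P deficiency all came from that replicate, so -9.62 is not a measured size. A far more strongly expressed D14 receptor gene (Sobic.001G465100), chosen after its values were seen, went the other way, with its values under Other observations. The signalling list had 3 of 14 members higher and 5 lower (adjusted p = 0.925). Among ABCG transporters, the family that includes known strigolactone exporters, ABCG38 (Sobic.003G281500) was 28.8-fold lower and ABCG41 (Sobic.008G033800) 38.7-fold lower, with 18 of 42 members lower and 6 higher (adjusted p = 0.0166; adjusted p = 0.206 with an estimated correlation).

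Outside these pathways, the libraries labelled P deficiency held more transcripts of a glycerate dehydrogenase (Sobic.004G001300, 34.1 ± 13.4 CPM against 0.0299, a ratio of 1140 with a counting interval of 403 to 5720) at day 4, with a log2 fold change of 13.31 without mock replicate 2 and 9.43 without mock replicate 3. All its mock counts at day 4 came from replicate 2, so 13.31 is not a measured size. A prolyl endopeptidase (Sobic.006G177800) was at 620 ± 94.2 against 9.9 ± 1.86 CPM. Also higher were the calcium-binding protein CML50 (Sobic.009G023300, 55.0 against 0.0746 CPM), a WAT1-related protein (Sobic.001G261408, 97.1-fold), the FCS-like zinc finger 15 (Sobic.004G199600, 68.7-fold) and polyol transporter 6 (Sobic.009G157800, 7.02 against 0.117 CPM).

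Photosynthesis genes were higher at day 4 in the libraries labelled P deficiency (24 of 43 higher, 3 lower, adjusted p = 4.63e-06; adjusted p = 0.0634 with an estimated correlation), with a photosystem I subunit (Sobic.009G229700) at 7.58 against 0.507 CPM. Cytokinin response and turnover genes were higher (12 of 21, 1 lower, adjusted p = 0.00126; 0.0988 with an estimated correlation), among them the response regulator ORR4 (Sobic.003G428300), at 152 against 42.3 CPM. Secondary wall genes were lower (29 of 44, 2 higher, adjusted p = 9.71e-09; 0.206 with an estimated correlation), with laccase-10 (Sobic.001G422300) at 0.178 against 89.3 CPM (log2 fold change -8.96, and -9.61 without P deficiency replicate 3). Sulfotransferases were lower (12 of 18, 1 higher, adjusted p = 0.000196; 0.206 with an estimated correlation), with cytosolic sulfotransferase 5 (Sobic.005G213600) 582-fold lower (log2 fold change -9.03, and -10.60 without P deficiency replicate 2). Auxin efflux carrier 9 (Sobic.003G327500) was at 1.18 against 46 CPM and flavonoid 3',5'-hydroxylase 1 (Sobic.001G360800) at 6.2 against 108 CPM.

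In all, 5094 of 25137 tested genes were higher and 4619 lower in the libraries labelled P deficiency at day 4 (edgeR, Benjamini-Hochberg adjusted p below 0.05), or 38.6% of genes. With a change of at least 2-fold required, 2046 were higher and 2636 lower. The median log2 fold change over all tested genes was 0.02.

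**Figure D2:**
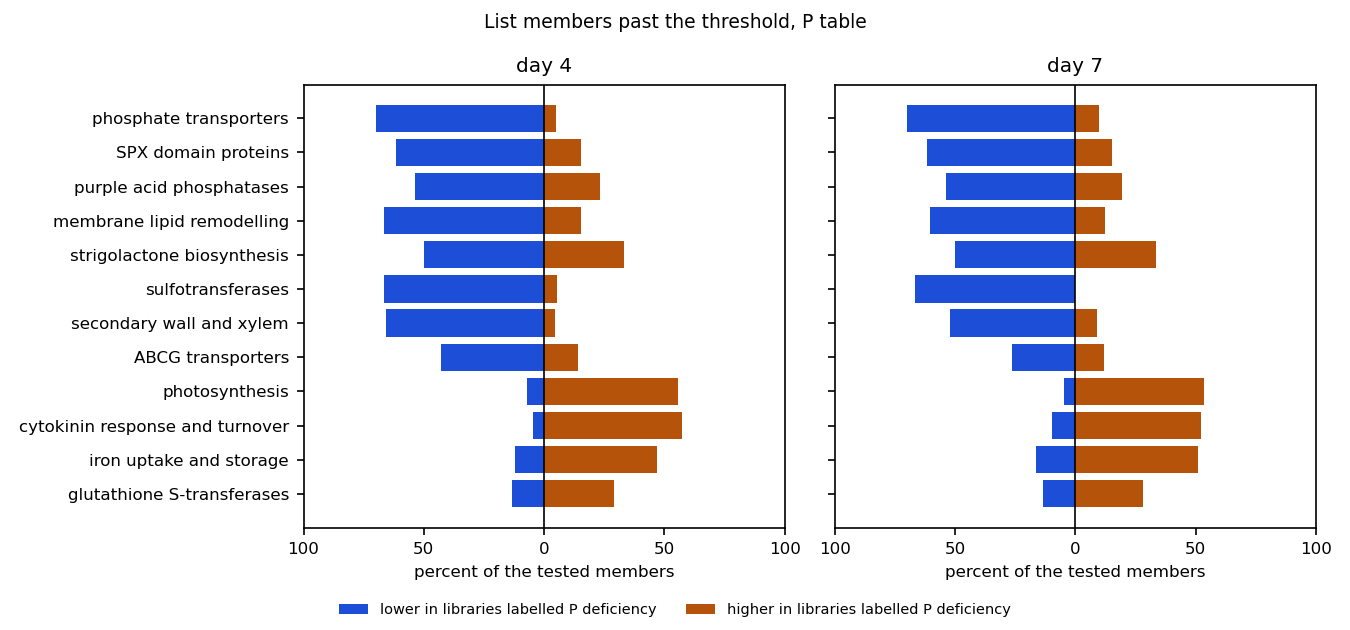
Members higher and lower in libraries labelled P deficiency, in percent of tested members, for gene lists at days 4 and 7 (edgeR adjusted p below 0.05). Of 20 phosphate transporters, 14 were lower at either day by the deposited labels, and no list median in the P table changed sign when scaling used total counts only.

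At day 7 the phosphate transporters, SPX domain proteins, purple acid phosphatases and lipid remodelling genes named here differed in the same direction as at day 4. SPX1 (Sobic.004G084900) was at 1.55 ± 0.0269 CPM in the libraries labelled P deficiency against 254 ± 9.6 in mock (log2 fold change -7.36 ± 0.14, SE, n = 3, edgeR adjusted p = 5.72e-12). SPX3 (Sobic.001G259100) was 793-fold lower, PHT1-3 (Sobic.001G234900) 287-fold lower, PAP15 (Sobic.007G091100) 1580-fold lower and SQD2 (Sobic.003G076900) 306-fold lower, at 5.88 against 1800 CPM. Purple acid phosphatase 22 (Sobic.008G036300) had 0 counts against 111 ± 21.0 CPM, at least 1270-fold lower. The ABC transporters B14 (Sobic.007G042600) and B15 (Sobic.006G123100) also had 0 counts in the libraries labelled P deficiency, at least 3560-fold and at least 723-fold lower. Non-specific phospholipase C4 (Sobic.001G008600) was 79.0-fold lower and ribonuclease 1 (Sobic.007G137700) 11.9-fold lower. Camera gave adjusted p = 7.93e-07 for the phosphate transporters (14 of 20 lower, 2 higher) and 3.91e-08 for membrane lipid remodelling (20 of 33 lower, 4 higher).

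Strigolactone genes kept their split at day 7, where the synthesis list again missed the threshold with camera (adjusted p = 0.0919) and passed as lower with fry (4.69e-06; 0.33 with an estimated correlation). CCD8-B (Sobic.003G293600) was at 1.25 ± 0.186 CPM in the libraries labelled P deficiency against 175 ± 64.1 in mock, and D27 (Sobic.005G168200) and CCD7 (Sobic.006G170300) were 44.3-fold and 15.1-fold lower. The CCD8-A gene (Sobic.005G002500) was 3.77-fold higher and the other D27 gene (Sobic.009G030800) 1.76-fold higher, a call that ended without P deficiency replicate 3 (log2 fold change 0.68) or mock replicate 2 (0.76). MAX2 (Sobic.010G043000) was at 201 against 73.1 CPM. Phytoene desaturase (Sobic.006G232600) of the carotenoid pathway was 4.0-fold lower. ABCG41 (Sobic.008G033800) was 56.3-fold lower and ABCG38 (Sobic.003G281500) 23.5-fold lower, though the ABCG list did not pass with camera at day 7 (adjusted p = 0.178; 0.00025 with fry, which called it lower, and 0.455 with an estimated correlation).

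Sorghum roots release sorgoleone, a quinone made in root hairs, and its synthesis list was lower at day 7 in the libraries labelled P deficiency (6 of 11 lower and 0 higher, adjusted p = 0.00436; 0.246 with an estimated correlation). Its O-methyltransferase (Sobic.010G234500) was at 169 ± 14.4 against 523 ± 149 CPM. The list was already lower at day 4 (4 of 11 lower and 0 higher, camera adjusted p = 0.0015, and 0.206 with an estimated correlation). This gene was 3.28-fold lower at day 4. Iron uptake and storage genes were higher in number (25 of 49 higher, 8 lower, adjusted p = 0.00436; 0.199 with an estimated correlation), while deoxymugineic acid synthase (Sobic.006G096400), which makes an iron chelator, was 7.17-fold lower. The iron list was also higher at day 4 (23 of 49 higher, 6 lower, camera adjusted p = 0.00666, and 0.206 with an estimated correlation). The CLE-related peptide gene ESR1-like (Sobic.010G156400) had 0 counts in mock and 10.7 ± 2.74 CPM in the libraries labelled P deficiency, at least 139-fold higher. MADS-box factor 51 (Sobic.003G073700) was 65.0-fold higher (log2 fold change 5.98, and 6.77 without mock replicate 1) and NAC factor 79 (Sobic.002G199200) at least 212-fold lower. Isopropylmalate synthase 2 (Sobic.008G012400), an enzyme of leucine synthesis, was 8.61-fold higher, and 7.23-fold higher at day 4.

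At day 7, 4386 genes were higher and 4572 lower in the libraries labelled P deficiency (35.6% of genes tested by edgeR), and 1724 and 2768 with at least 2-fold required. Across genes, the log2 fold changes of days 4 and 7 correlated with r = 0.858 (Spearman rho 0.811), genes not being independent replicates. At both days 3439 genes were higher, where 889 would be shared by chance, and 3463 were lower, against 840 by chance. Only 9 genes were higher at day 4 and lower at day 7, and 14 went the other way.

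Whether the response differed between the days was tested by the interaction, which 117 genes passed (edgeR). The vacuolar iron transporter 2 (Sobic.002G194600) was at 152 against 20.2 CPM at day 4 in the libraries labelled P deficiency and mock, and at 16.3 CPM, 1.23-fold below mock, at day 7, where the difference missed the threshold (adjusted p = 0.38; interaction adjusted p = 0.00187). Peroxidase 1 (Sobic.002G003500) was at 13.9 against 3.12 CPM at day 4 and 41.4 against 0.322 CPM at day 7 (interaction adjusted p = 0.00582). DESeq2 gave 416 genes. Without single libraries the interaction count ranged from 58 (without mock day 7 replicate 2) to 180 (without mock day 7 replicate 1), and was 60 without P deficiency day 4 replicate 2.

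In mock alone, 213 genes were higher and 125 lower at day 7 than at day 4 (edgeR). Clock and light genes, chosen after their values were seen, were among them: LHY (Sobic.007G047400) was at 132 ± 44.7 against 7.66 ± 1.16 CPM, REVEILLE 2 (Sobic.010G275700) at 20.1 against 4.13 CPM and the light-inducible factor CPRF2 (Sobic.008G157100) at 24.2 against 4.52 CPM. The iron transporter Fe(2+) transport protein 1 (Sobic.001G142800) was at 13.0 against 68.5 CPM. The total of 338 became 743 without mock day 7 replicate 1 (307 higher and 436 lower) and 66 without mock day 4 replicate 3 (31 higher and 35 lower). The larger share of increases thus did not hold without either of these libraries. The hour of sampling is not given in the sources used here.

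GR245DS raised transcripts of its own signalling repressors at 3 h. SMAX1 and DWARF 53 (D53) proteins repress responses to karrikins and strigolactones and are degraded when the signal is perceived. SMAX1 (Sobic.004G325000) rose from 30.2 ± 10.2 CPM in mock to 101 ± 15.4 with GR245DS (log2 fold change 1.74 ± 0.22, SE, n = 3, edgeR adjusted p = 0.00352). D53 (Sobic.008G002400) rose from 51.1 to 155 CPM. A second D53 gene (Sobic.005G002400) and a SMAX1-like gene (Sobic.007G090900), chosen after their values were seen, rose from 40.4 to 148 CPM and from 184 to 312 CPM. The strigolactone signalling list was higher with camera (4 of 14 higher, 0 lower, 6 higher adjusted over the list alone, adjusted p = 1.24e-05; adjusted p = 0.187 with an estimated correlation).

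Detoxification genes also rose at 3 h. Glutathione S-transferases attach glutathione to reactive or foreign compounds, and GSTU17 (Sobic.001G319500) rose from 6.18 ± 0.802 to 1300 ± 983 CPM and GSTU6 (Sobic.001G319700) from 0.392 to 47.3 CPM. A further glutathione S-transferase (Sobic.003G426400) rose 6.32-fold and IN2-1 (Sobic.001G412700) 32.8-fold. Of 99 glutathione S-transferases 19 were higher and 0 lower (32 higher adjusted over the list alone, adjusted p = 2.37e-16; adjusted p = 0.187 with an estimated correlation). UDP-glycosyltransferases had 11 of 85 members higher and 0 lower (adjusted p = 2.06e-07; adjusted p = 0.187 with an estimated correlation), among them UGT 83A1 (Sobic.001G084400), from 30.2 to 176 CPM. Cytochrome P450 709B2 (Sobic.002G388900) rose 17.1-fold, in a list with 14 of 248 members higher (adjusted p = 0.00283; adjusted p = 0.696 with an estimated correlation).

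Among the largest increases at 3 h were 4 genes described as reductases, with a wide spread between replicates, and reductases were not tested as a list. A salutaridine reductase-like gene (Sobic.004G304300) was at 35.4 ± 42.4 CPM against 0.0522 (log2 fold change 9.28 ± 1.39, SE, n = 3, edgeR adjusted p = 0.00861), and its call ended without mock replicate 3 (8.72). Aldo-keto reductase 3 (Sobic.010G117900) rose 260-fold and 12-oxophytodienoate reductase 1 (Sobic.010G084400) 178-fold. A tropinone reductase homolog (Sobic.005G055300) was 314-fold higher, but missed the threshold without GR245DS replicate 2 (log2 fold change 6.92), mock replicate 2 (7.71) or mock replicate 3 (7.71). GR245DS replicate 2 carried much of the size of these increases. Without it the log2 fold change was 7.61 in place of 9.28 for Sobic.004G304300, 6.79 in place of 8.01 for Sobic.010G117900, 6.80 in place of 7.45 for Sobic.010G084400, 6.94 in place of 7.71 for GSTU17 and 6.17 in place of 6.90 for GSTU6. Mock libraries near 0 counts moved these folds as well: without mock replicate 2 they were 13.23 for Sobic.004G304300 and 8.41 for Sobic.010G084400, and without mock replicate 1 13.63 for Sobic.005G055300. For Sobic.004G304300 and Sobic.005G055300 the remaining mock libraries then held 0 counts, so 13.23 and 13.63 are not measured sizes.

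Regulators were also among the genes higher at 3 h. WRKY24 (Sobic.009G100500) rose from 110 ± 18.8 to 241 ± 14.5 CPM, in a list with 5 of 81 members higher and 0 lower (adjusted p = 0.0012; adjusted p = 0.187 with an estimated correlation). The auxin-responsive gene IAA25 (Sobic.007G009300) rose from 3.98 to 10.1 CPM, heat shock protein HSP70-4 (Sobic.009G163900) from 39.6 to 134 CPM, and the transporter ABCG53 (Sobic.002G174000) from 52.1 to 124 CPM. The call of IAA25 ended whichever of the 6 libraries was left out (log2 fold change 1.26 to 1.45). The call of HSP70-4 ended without any library but GR245DS replicate 3 (1.34 to 1.99), and that of ABCG53 in the same 5 cases (1.03 to 1.44). With total counts only, IAA25 (1.2), HSP70-4 (1.62) and ABCG53 (1.10) all lost their calls, and ABCG53 also with RLE (1.25). A malonyltransferase of anthocyanin glucosides (Sobic.003G260000) rose 4.1-fold.

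Growth-related lists were called slightly lower at 3 h by camera with its preset correlation, but not with an estimated one. No single member passed the threshold. Cytosolic ribosomal proteins had a median log2 fold change of -0.23 (camera adjusted p = 1.44e-09; adjusted p = 0.719 with an estimated correlation), with 0 of 217 members past the threshold by edgeR, 11 at an unadjusted p below 0.05 and 0 by DESeq2. Expansins, which loosen cell walls, had a median of -0.29 (0.000409; 0.894 with an estimated correlation), with 0 of 63 members past the threshold by edgeR, 0 at an unadjusted p below 0.05 and 0 by DESeq2. Of all 24814 genes tested at 3 h, 1963 had an unadjusted p below 0.05 by edgeR.

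Strigolactone synthesis genes were not among the calls at 3 h (0 of 7 past the threshold by edgeR, 0 at an unadjusted p below 0.05 and 0 by DESeq2, list adjusted p = 0.996, list median -0.1 and mean 0.05 on the log2 scale). CCD8-B (Sobic.003G293600) was at 0.744 ± 0.541 CPM with GR245DS and 0.575 ± 0.434 in mock, and CCD7 (Sobic.006G170300) at 0.302 against 0.349 CPM (log2 fold changes 0.37 ± 0.95 and -0.20 ± 1.19, SE, n = 3).

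**Figure D3:**
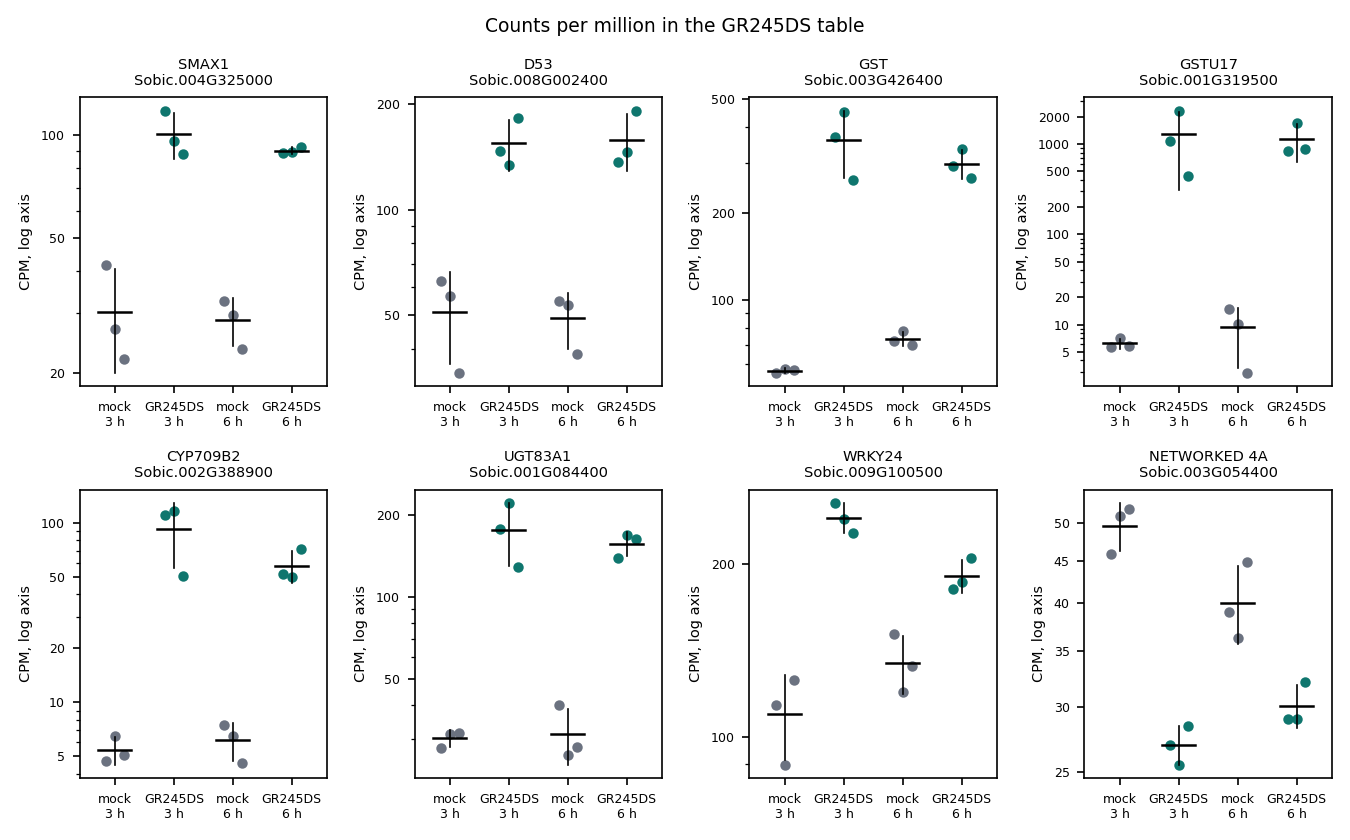
CPM on a log axis of GR245DS-responsive genes in the 12 libraries of the GR table, by treatment and time. Points are libraries and marks with bars the mean and SD of 3 libraries, and SMAX1 rose from 30.2 to 101 CPM at 3 h.

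At 3 h, 247 of 24814 genes were higher with GR245DS and 3 lower (edgeR). With the replicate number as a block these were 634 and 143, and with DESeq2 519 and 70. The 3 lower genes were NETWORKED 4A (Sobic.003G054400), from 49.5 to 27 CPM, and 2 genes with no description chosen after their values were seen, Sobic.004G077200 (8.06 to 3.59 CPM) and newGene_595 (16.5 to 9.45 CPM). NETWORKED 4A missed the threshold without mock replicate 2 (log2 fold change -0.83, against -0.88 with it). Without single libraries the total of 250 became 138 and 135 (GR245DS replicates 1 and 2), and 160, 122 and 164 (mock replicates 1 to 3).

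At 6 h the signalling repressors and detoxification genes stayed high. SMAX1 (Sobic.004G325000) was at 89.9 ± 2.12 CPM with GR245DS against 28.6 ± 4.56 in mock (log2 fold change 1.65 ± 0.22, SE, n = 3, edgeR adjusted p = 0.00833). D53 (Sobic.008G002400) was at 159 against 48.9 CPM, a call that ended without mock replicate 2 (log2 fold change 1.77) or 3 (1.55). GSTU17 (Sobic.001G319500) was at 1150 ± 512 against 9.33 ± 6.03 CPM and GSTU6 (Sobic.001G319700) 45.8-fold higher. Monooxygenase 2 (Sobic.001G500200), not named at 3 h, was 41.5-fold higher. Another gene described as UGT 83A1 (Sobic.001G044400), not the one named at 3 h, was 8.33-fold higher. Camera called the signalling list (3 of 14 higher, 5 adjusted over the list alone, adjusted p = 1.04e-06; 0.191 with an estimated correlation). Glutathione S-transferases had 13 of 99 members higher (26 adjusted over the list alone, adjusted p = 9.76e-17; 0.304 with an estimated correlation).

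Single enzyme genes of other pathways were also called at 6 h. A deoxyxylulose phosphate synthase 2 gene (Sobic.002G064500), not the one named for the P table, rose from 6.81 ± 1.92 to 28.4 ± 1.47 CPM. Deoxymugineic acid synthase (Sobic.006G096400) rose from 34.7 to 363 CPM, though its call ended without any library but GR245DS replicate 3 (log2 fold change 3.06 to 3.64). A cinnamyl alcohol dehydrogenase (Sobic.002G195400) was 37.2-fold higher, a call that ended without GR245DS replicate 1 or 2 or mock replicate 2 or 3 (4.90 to 5.18). Pectinesterase 2.1 (Sobic.003G321200) was the only gene that fell by edgeR without the replicate block, from 14.8 to 4.46 CPM, against 129 genes with the block. Pectinesterase 2.1 missed the threshold whichever of the 6 libraries was left out (log2 fold change -1.89 to -1.63). None of the 7 strigolactone synthesis genes was called (0 of 7 by edgeR, 0 at an unadjusted p below 0.05 and 0 by DESeq2, list adjusted p = 0.736).

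At 6 h, 119 genes were higher and 1 lower with GR245DS (edgeR), against 380 and 129 with the replicate block and 278 and 50 with DESeq2. Without single libraries the total of 120 became 75, 65 and 75 (GR245DS replicates 1 to 3) and 90, 52 and 59 (mock replicates 1 to 3). Of the 247 and 119 higher genes 112 were shared, where 1.18 would be by chance. Fold changes at 3 h and 6 h correlated across genes with r = 0.557 (rho 0.426). No gene passed the interaction of treatment and time (edgeR 0, with 289 at an unadjusted p below 0.05, and DESeq2 0). Mock at 6 h against 3 h gave 0 genes with edgeR (344 at an unadjusted p below 0.05) and 5 with DESeq2.

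**Figure D4:**
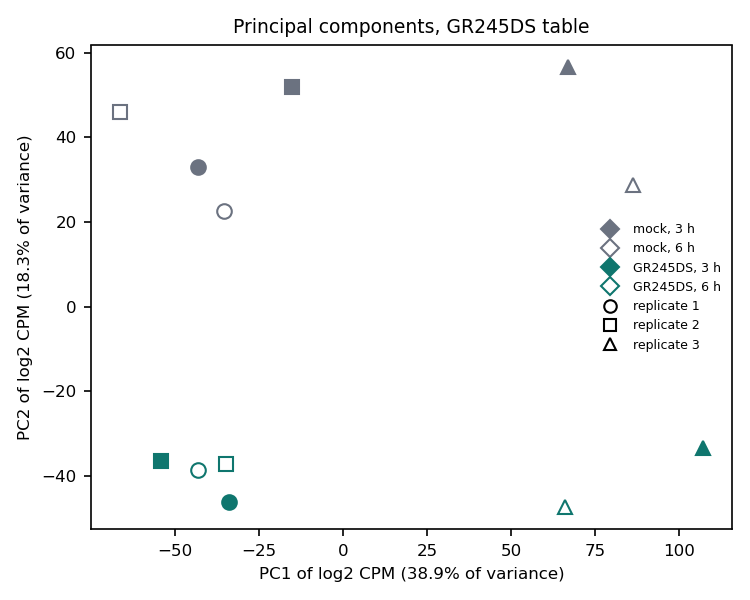
Principal components of the 12 libraries of the GR table, by treatment, time and replicate number, with the percent of variance on each axis. The first component, with 38.9% of the variance, separates the third replicates, and the second, with 18.3%, separates GR245DS from mock.

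Fold changes in the P and GR tables were weakly and negatively correlated by the deposited labels. Across 23098 genes tested in both r lay between -0.103 and -0.068. Of the genes higher with GR245DS at 3 h, 67 were lower in the libraries labelled P deficiency at day 4 (41.6 by chance) and 56 were higher (46.8 by chance), and at day 7 these were 67 (40.9) and 45 (40.2). Of the genes higher with GR245DS at 6 h, 36 were lower at day 4 (19.5 by chance) and 25 higher (21.9), and 39 were lower at day 7 (19.2) and 20 higher (18.8). With the P labels turned, the larger overlaps would be between genes higher in both tables. Deoxymugineic acid synthase (Sobic.006G096400) was lower in the libraries labelled P deficiency, at 15.2 against 72.2 CPM at day 4, and higher with GR245DS at 6 h. The phosphate transporter list did not pass with GR245DS at 3 h (adjusted p = 0.976) or 6 h (adjusted p = 0.167), with 0 of 17 members past the threshold by edgeR, 1 at an unadjusted p below 0.05 and 0 by DESeq2 at either time.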

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

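The interaction test and the values under total-count scaling, with the replicate block and without single libraries were planned, while their use to weigh explanations and all other tests in this part were chosen after the result was seen. The response in the libraries labelled P deficiency differed between day 7 and day 4 for 117 genes, by the edgeR test of the interaction. The 6 named genes were picked out because their responses differed between the days by that test. The Bowman-Birk trypsin inhibitor (Sobic.005G215766) was at 0.338 against 5.31 CPM in mock at day 4 and 1.24 against 0.568 CPM at day 7 (day 7 adjusted p = 0.181), a log2 difference of 5.08. Peroxidase 1 (Sobic.002G003500) differed by 4.9 and the CCCH zinc finger 37 (Sobic.009G205100) by 3.78, the latter being at 0.387 against 15.1 CPM at day 4 and 14 against 38.3 CPM at day 7. Glycerate dehydrogenase (Sobic.004G001300) differed by -5.41, from 34.1 against 0.0299 CPM to 7.82 against 0.308 CPM. The oxidase GLO5 (Sobic.002G036000) differed by -3.31, from 1.9 against 10.5 CPM to 0.245 against 13.5 CPM. The vacuolar iron transporter 2 (Sobic.002G194600) differed by -3.21.

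Of 100 splits of the samples for the interaction in the P table, the real one included, 8 gave at least 117 genes. Most of the others among these moved unequal numbers of libraries labelled P deficiency and mock between the days. Changes with time do not cancel in such splits, so the splits cannot decide on chance, which was not excluded. The highest other split gave 1473 genes, several times the real count, which points to a structure of the samples. That split exchanges the days of all 6 libraries labelled P deficiency and of 0 mock libraries, so by construction changes with time shared by both groups enter its contrast. The calls of the trypsin inhibitor and of glycerate dehydrogenase ended without 8 and 6 single libraries (4.43 to 5.19 and -5.49 to -4.78). Without mock day 4 replicate 2 the difference for glycerate dehydrogenase was -8.67, and without P deficiency day 4 replicate 2 that for the CCCH zinc finger 37 was 4.93. The mock libraries left at day 4 then held 0 counts of glycerate dehydrogenase, so -8.67 is not a measured size.

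Most called genes of 4 phosphate starvation lists were lower in the libraries labelled P deficiency. An exchange of the mock and P deficiency labels in the deposited P table stays open: of called members of other lists, strigolactone biosynthesis and ribonucleases, 70% were also lower at day 4, but these are 7 of 10 genes, against 47.6% of all calls (exact binomial test, one-sided, p = 0.135, and p = 0.0624 for 8 of 10 at day 7). The test treats these genes as independent and counts direction only, not size, so it cannot decide the question. A few mislabelled libraries are excluded, since 0 libraries labelled P deficiency reached the lowest library labelled mock, and scaling is excluded because 78.9% of called phosphate list members were lower with total counts only. In the GR table, 90.4% of the lower members had mock levels nearer those of the libraries labelled P deficiency, against 64.8% of the other lower genes. The mock levels of these lower members had a median log2 gap of 0.09 to the libraries labelled P deficiency and -3.09 to those labelled mock. The phosphate supply of that experiment is not stated, so correct labels with lower phosphate genes under P deficiency stay open too.

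The third replicates of all 4 groups of the GR table stood apart on the first principal component. The deviations of the third replicates of different groups correlated with an r of at least 0.439, as a batch shared by them would give. This largely restates that they stood apart together, so it cannot tell a batch from a biological difference. Sequencing depth is excluded, since the third replicates of all 4 groups had total counts within the range of the others. The labels give no date or batch, and no biological explanation was tested.

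Nearly all GR245DS calls were increases. Scaling is excluded as the whole cause, since 90.8% of calls at 3 h were increases with total counts only. With the replicate number as a block 18.4% of calls at 3 h were decreases, so decreases hidden by the spread between replicate numbers may be part of the cause. A biological preponderance of increases stays open.

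For comparisons of 3 against 3 libraries there are 10 splits, the real one included, too few for a share under 0.1. The number of splits with a result as large was 1 in each of day 4 (9713 genes, highest other split 0), day 7 (8958, highest other 0), mock at day 7 against day 4 (338, highest other 1), GR245DS at 3 h (250, highest other 0) and at 6 h (120, highest other 0). For the GR245DS comparisons 4 of the splits part all replicate pairs, and the others among these gave 0 genes. For the interaction in the GR table, with 0 genes, all 100 splits gave as many (highest other 2000, which points to a structure of the samples), and for mock at 6 h against 3 h all 10 did (highest other 0). The split with 2000 genes puts the third replicates of either treatment together, at opposite times, but other splits of this kind gave at most 1 gene, so what produced it stays open.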

How the results depend on the processing

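Leaving out the third replicates of all GR groups was chosen after seeing the data, and the other alternatives before. The cause was not tested for any change below unless stated.

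In the P table, the counts of genes higher and lower at either day stayed within 1.5 times the reported count under RLE, total counts, DESeq2, both filters, the fit of 2 groups, the replicate block and without each library. Requiring at least 2-fold, a stricter threshold by construction, gave 2046 higher and 2636 lower at day 4 and 1724 and 2768 at day 7. The replicate block gave 9305 genes at day 4 and 8447 at day 7. In the P table the replicate numbers do not pair the samples clearly (r between -0.288 and 0.463). The block ended the day 4 call of the D27 gene Sobic.009G030800 and the interaction calls of Sobic.005G215766 (4.87) and Sobic.004G001300 (-5.32). The interaction count of 117 became 71 with the block, 416 with DESeq2 and 58 to 180 without single libraries. It was 180 without mock day 7 replicate 1, 58 without mock day 7 replicate 2, 60 without P deficiency day 4 replicate 2, 68 and 73 without mock day 4 replicates 2 and 1, and 72 and 75 without P deficiency day 7 replicates 2 and 1. Mock at day 7 against day 4 gave 338 genes, 210 with at least 2-fold, 862 with DESeq2, 176 with only the groups compared and 66 to 743 without single libraries.

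In the GR table, increases at 3 h numbered 247, and 634 with the block, 519 with DESeq2, 100 with only the groups compared and 122 to 301 without single libraries. Decreases at 3 h numbered 3, and 143 with the block, 70 with DESeq2, 18 with total counts, 16 without the third replicates, 1 with no filter, 1 with at least 2-fold, 0 with only the groups compared and 0 to 4 without single libraries. Increases at 6 h numbered 119, and 380 with the block, 278 with DESeq2 and 52 to 89 without single libraries. Decreases at 6 h numbered 1, and 129 with the block, 50 with DESeq2, 9 without the third replicates, 4 with total counts, 3 with no filter, 2 with the stricter filter and 0 to 1 without single libraries. The block and DESeq2 kept all 250 genes at 3 h and all 120 at 6 h. Mock at 6 h against 3 h gave 0 genes with edgeR and 5 with DESeq2. Total-count scaling moved the median of all genes to -0.15 at 3 h and -0.11 at 6 h on the log2 scale. The correlation of 3 h and 6 h was 0.905 over genes called in either. The other agreements kept their sign.

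Strigolactone synthesis genes, none of them called in the GR table, changed sign without single libraries, with these ranges of log2 fold change. At 3 h these were Sobic.007G170300 (-0.04 to 0.79), Sobic.005G168200 (-0.66 to 0.03), Sobic.003G293600 (-0.14 to 0.87) and Sobic.006G170300 (-0.79 to 0.29). At 6 h they were Sobic.007G170300 (-0.62 to 0.56), Sobic.009G030800 (-0.53 to 0.29), Sobic.005G002500 (-0.41 to 0.76) and Sobic.006G170300 (-1.13 to 0.64).

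With fry, 1 of 20 list calls at day 4, 0 of 15 at day 7, 10 of 14 at 3 h and 10 of 11 at 6 h ended, and 6 lists at day 4, 10 at day 7 and 0 at 3 h and 6 h gained a call. The gains include strigolactone biosynthesis at both days, and the ABCG transporters and strigolactone signalling at day 7. Over the called named genes and all alternatives, 553 values kept direction and call at day 4 and 6, all of the D27 gene Sobic.009G030800, lost the call. At day 7 these were 492 and 2, at 3 h 213 and 39 (10 genes), at 6 h 186 and 38 (8 genes), and for the interaction 92 and 16 (2 genes). Genes not called gained a call in 12 values (5 genes) at 3 h, 9 (4 genes) at 6 h and 1 at day 7.

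Of the named genes, SMAX1 (Sobic.004G325000) kept its call without each library at both times, and at 3 h its call ended only in the fit of the 2 groups compared, as did those of D53 (Sobic.008G002400) and WRKY24 (Sobic.009G100500). Not called as reported, but called with the block and with DESeq2, were at 3 h ABCG36 (Sobic.003G216232, log2 fold change 2.75 with the block), GH3.8 (Sobic.002G361500, 0.79), scarecrow-like 9 (Sobic.002G301800, 0.66) and a glutathione peroxidase (Sobic.006G173900, 0.67), and at 6 h ABCG53 (Sobic.002G174000, 1.24) and Peroxidase 1 (Sobic.003G151900, -1.19). The block without DESeq2 also called ribosomal protein L10 (Sobic.001G177800, 0.86) at 3 h, and at 6 h another ABCG36 gene (Sobic.003G216000, 2.63) and histone H1 (Sobic.010G021300, -1.04). The flavonoid list at 3 h had adjusted p = 0.0364 and 0.0515 with the block, and the carotenoid and MEP pathway list at 6 h 0.0498 and 0.0584. The block added calls for the organic acid list at 3 h and the auxin transport, nitrate transporter and photosynthesis lists at 6 h, and changed no other list call or named gene call at 3 h or 6 h. For the GR interaction it added calls for 4 lists (photosynthesis, histones, phosphate transporters and SPX domain proteins), and for mock at 6 h against 3 h it added 3 and ended 1. Genes at low levels were called where the change was large, such as GSTU6 (Sobic.001G319700) from 0.392 CPM in mock at 3 h, and depth was not tested as a limit.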

Other observations

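CYP711A genes, whose products oxidise the strigolactone precursor carlactone, were chosen after their values were seen. Sobic.003G269500 was at 3.25 ± 1.52 CPM in the libraries labelled P deficiency against 80.2 ± 6.24 in mock at day 4 (log2 fold change -4.62 ± 0.32, SE, n = 3, edgeR adjusted p = 2.64e-07) and at 1.65 against 89.7 CPM at day 7. Sobic.004G095500 was at 0.848 against 12.7 CPM at day 4 and 0.714 against 13.9 CPM at day 7. Sobic.003G269600 was 1.47-fold lower at day 4 and 2.28-fold lower at day 7. Sobic.010G170400 missed the threshold at day 4 (adjusted p = 0.182) and was 2.92-fold lower at day 7. In the GR table none of the 4 was called, with Sobic.003G269600 at 22.9 ± 13.0 CPM with GR245DS against 8.25 ± 0.484 in mock at 3 h (adjusted p = 0.132). The D14 receptor gene Sobic.001G465100, also chosen after its values were seen, was at 408 ± 46.2 against 137 ± 9.01 CPM at day 4 in the libraries labelled P deficiency and mock.

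The third replicates of the GR table were compared with the other libraries, a test chosen after they were seen to stand apart. Of 24814 genes 4103 were higher and 4555 lower (edgeR). Photosynthesis genes were higher in 45 of 57 cases, while 41 of 63 expansins, 29 of 45 secondary wall genes and 7 of 10 nitrate transporters were lower. With an estimated correlation the camera adjusted p was 0.233 for photosynthesis, 0.458 for expansins, 0.369 for secondary wall genes and 0.279 for nitrate transporters, so none of these 4 lists was called under that setting. With the third replicates left out, GR245DS gave 350 increases and 16 decreases at 3 h, with 207 of the 250 genes shared, and 124 and 9 at 6 h, with 90 of the 120 shared.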
